A study of Gallus gallus with 16 samples.

How the data were processed

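Total RNA from the jejunum of 16 male broilers, 4 on each of 4 diets, was isolated with Qiazol and RNeasy columns, copied with the Ambion WT Expression Kit, and labelled with biotin by the Affymetrix WT Terminal Labeling Kit for 1-colour arrays, per the labels' protocols. Every array is a separate bird, per the series' design text, so limma's p-values for genes measure the spread between birds. The birds of a diet come in pairs with neighbouring numbers in the sample titles. The labels do not say whether such birds shared a pen, and the main fit treats them as independent. The version 1.1.1 of GCOS is named per the submitters' processing notes. Values between 0.79 and 14.48 were taken from the deposited series table and read as log2 intensities. The summarization, normalization, any filter and the base of the logarithm are not given in the sources used here. The base was taken as 2 because the range and the medians match log2 summaries of scanner values, and a fold change rests on that reading. Nearly equal quartiles on all arrays show that the values had been scaled between arrays, and no centring per probe set was seen. No measure of signal over background is used here, so low values were kept. The lower quartiles of the arrays lay between 4.447 and 4.611. Some genes named below had diet means near or under these, among them LGR5, RIMBP2, CLCA2, TAL1, LOC420748, DPT, OGN, CINP, MIR20B and ANKRD31. Background may enter the differences of such genes.

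Genes were named through GEO's platform annotation of the probe sets, which can be old. Of 20804 probe sets 12300 had 1 symbol, 256 had several and 8248 (39.6%) had none in that table, and none was named from a probe set with several. Entrez numbers of 11727 of the named probe sets were found in the RefSeq gene table, and 0 symbols differed. A gene with several probe sets was represented by the one with the highest mean over all arrays. Of all probe sets, 1644 had exactly the same 16 values as another one, in 749 sets that leave 19909 distinct profiles, and 18 of them were named. These were kept in the tests, so counts of probe sets are not counts of independent transcripts.

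The analysis used R 4.3.3 with limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. One linear model with a mean per diet was fitted to all 16 arrays, so that all groups share one estimate of the spread. Empirical Bayes moderation (lmFit, eBayes) gave a moderated F test over the 4 diets and 6 pairwise contrasts, each adjusted by Benjamini-Hochberg over all 20804 probe sets with a threshold of 0.05 on the adjusted p. Differences are written as the later letter minus the earlier one, and every adjusted p of a gene is limma's. This fit had no covariate.

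Gene lists for transport, digestion, metabolism, immunity, cell types and general processes of the intestine were fixed before the data were examined, as were the tests, the naming rule and the first set of alternatives. Of 39 lists 38 had at least 5 measured members, between 8 and 59. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 38 lists. They were tested again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. Camera sets the genes of a list against all other genes. With the preset correlation its p takes little account of members varying together between birds, so it does not measure the spread between birds. The array means of each list were also compared by exact permutation, where the smallest possible two-sided p is 0.0286. A list's level on an array is the mean over its members, and "adjusted over the list alone" means Benjamini-Hochberg over the members of that list. The list left out, of W chromosome genes, had 1 measured member, HINTW, with a mean of 4.76 (range 3.90 to 5.17), at the 28.9th percentile of all probe sets in birds that the labels give as male.

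Genes were named in the text by a fixed rule: for the test over all diets, the 24 smallest p among passing probe sets with 1 symbol, or the 12 smallest where fewer passed; for a pair, the 6 higher and 6 lower with the largest fold change among those passing, filled to 3 per direction with the smallest p; for a list described, up to 4 members with the smallest p, of which 2 are given; and always SLC5A1 and SLC15A1. Genes filled in this way did not pass and are given as values.

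The procedure was tested on simulated data with the spread of the real arrays and 200 of 20804 probe sets changed. At a log2 size of 1, between 68% and 82% of the changed probe sets were recovered in the 6 comparisons, and at a size of 2 between 95% and 98%, with 7 to 15 false calls. A list shifted by 0.5 was called in each comparison, and no other list was. That simulation draws genes independently, so it does not show how camera behaves when the genes of a list vary together between birds.

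The alternatives were quantile normalization, median centring, leaving out the lowest 25% or 50% of probe sets or those without a single symbol, a trended and robust variance, array weights, the title number range as a block, neighbouring title numbers as a random block, the arrays of the compared diets only, other thresholds, leaving out each bird, and for lists the mean of a gene's probe sets. Sample titles carry numbers whose meaning the labels do not give, so the 2 ranges are no stated batch. Added after seeing the data were the title number as a linear covariate, 1 copy of identical probe sets, leaving out the 2 arrays with the lowest weights, and a fit within each range.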

Results

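Gene expression was measured in the jejunum, the middle stretch of the small intestine, of male broiler chickens on day 21. Each of 16 birds gave one array, and the birds had been fed one of 4 diets that the labels call A, E, F and H, with 4 birds per diet. The series title speaks of a blend of essential oils from star anise, rosemary, thyme and oregano, of saponins, and of bird performance and ileal protein digestibility. The labels do not say which additive each letter stands for or which letter is the control, so all 6 pairs of diets were compared and no letter served as a reference. The question behind the comparisons is which jejunal genes differ in level between birds on these diets. The table held values, read as log2, for 20804 probe sets, of which 12300 carried a single gene symbol. Array medians lay between 5.94 and 6.10. The mean correlation between arrays, across probe sets, was 0.977 within diets and 0.976 between diets. Precision is limited by the 4 arrays per diet.

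Across the 4 diets together, the gene that stood out was PURG, a purine-rich element binding protein. Its mean log2 level was 6.24 ± 0.15 in diet A, 6.49 ± 0.12 in diet E, 6.71 ± 0.12 in diet F and 7.12 ± 0.05 in diet H (SD, n = 4 each). TMEM86A, a lysoplasmalogenase, had a mean of 8.92 ± 0.45 in diet A against 10.23 ± 0.41, 10.02 ± 0.40 and 10.19 ± 0.34 in diets E, F and H (SD, n = 4). ERRFI1, a feedback inhibitor of the epidermal growth factor receptor, had means of 8.77 ± 0.43, 9.08 ± 0.20, 9.39 ± 0.29 and 9.82 ± 0.18 in diets A, E, F and H (SD, n = 4). The remaining probe sets with a single symbol and the smallest p were LOC420748, DPYS, LUZP1, LOC426897, ABHD11, CHMP4B, HIGD2A, LOC427882 and MRPS10. DPYS encodes dihydropyrimidinase of pyrimidine breakdown, CHMP4B a subunit of the ESCRT-III membrane complex, and MRPS10 a mitochondrial ribosomal protein. No gene passed the moderated F test of limma over the 4 diets, with 0 of 20804 probe sets at an adjusted p under 0.05 and 1696 at an unadjusted p under 0.05, where 1040 would be expected by chance. The smallest adjusted p was 0.0632, for PURG, and the other 11 of the named genes had adjusted p between 0.425 and 0.581. PURG was called in this test under 6 of the other settings tried, among them leaving out the lowest 25% of probe sets (limma adjusted p = 0.0389).

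**Figure D1:**
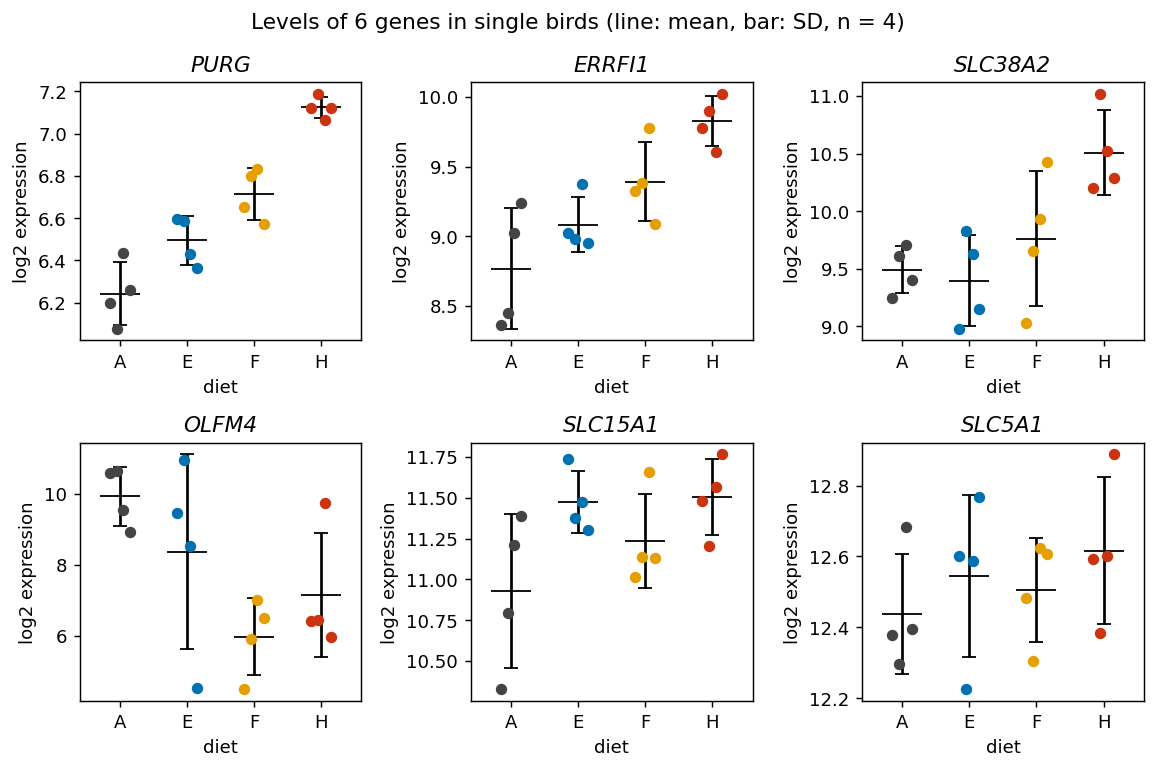
Log2 expression (vertical axis) of 6 genes in single birds by diet (horizontal axis); points are birds, the line is the mean and the bar the SD of 4 birds. PURG had means of 6.24 in diet A and 7.12 in diet H, and SLC5A1 had means between 12.44 and 12.62 in the 4 diets.

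Between diets A and H, PURG was higher in diet H, with a log2 fold change of 0.88 (SE 0.104, limma adjusted p = 0.00738), and all 4 birds on diet H lay above all 4 on diet A. ERRFI1 had a log2 difference of 1.06 (SE 0.197) and LUZP1, a leucine zipper protein, one of 0.72 (SE 0.141), each with a limma adjusted p of 0.197. On the lower side, LOC427882 differed by -1.77 (SE 0.362), LOC426897 by -0.79 (SE 0.152) and PDE12, a mitochondrial phosphodiesterase that trims poly(A) tails, by -0.57 (SE 0.121), with the same adjusted p of 0.197. With the title number range as a block, ERRFI1, LUZP1, LOC427882, LOC426897 and PDE12 were called (limma adjusted p 0.0428 to 0.0436). With the title number as a linear covariate they were not (limma adjusted p 0.363 to 0.439). The messages of the cytosolic ribosome lay lower in diet H: 51 of 52 measured ribosomal protein genes had a negative difference, with a median of -0.49, and the array mean of the list was 9.57 ± 0.15 against 10.06 ± 0.26 in diet A (SD, n = 4). RPL24 and RPL23A differed by -0.72 and -0.67.

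PURG was 1 call among 20804 probe sets in limma, and 2398 had an unadjusted p under 0.05. The count became 0 without diet H replicate 2, where the adjusted p of PURG was 0.0563, and 2 without diet A replicate 1. With only the arrays of diets A and H in the fit it was 0, and the adjusted p of PURG was 0.216. With neighbouring title numbers as a random block (estimated correlation 0.173), the limma adjusted p of PURG was 0.025 between diets A and H and 0.211 over the 4 diets. No ribosomal protein gene passed over all probe sets, and 41 of the 52 passed when adjusted over the list alone. The camera test called this list (adjusted p = 1.56e-28), and the call was lost with adjusted p = 0.366 with an estimated correlation.

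Proliferation genes were also lower in diet H than in diet A. All 53 cell cycle genes had a negative difference, with a median of -0.63, among them the licensing factor CDT1 at -0.37 and ESPL1, the separase that splits sister chromatids, at -0.38. The mean of ESPL1 was 11.19 in diet A, where the mean of the list was 6.49. Whether its probe set reads only this gene was not tested. None of the 53 genes passed over all probe sets or adjusted over the list alone, and 20 had an unadjusted p under 0.05. Without diet H replicate 3 the median was -1.04, and without diet H replicate 4 it was -0.37. The camera adjusted p was 3.11e-14, and the adjusted p = 0.577 with an estimated correlation. Of 23 crypt stem and progenitor genes 18 lay lower, with LGR5, the marker of crypt base stem cells, at -0.62 and the chloride importer SLC12A2 at -0.69 (camera adjusted p = 0.00102; adjusted p = 0.366 with an estimated correlation). The means of LGR5, 4.435 in diet A and 3.815 in diet H, lay under the lower quartile of every array (4.447 or higher), so background may enter its difference. Fibroblast and matrix genes lay lower as well, 27 of 30 of them, with dermatopontin (DPT) at -1.42 and osteoglycin (OGN) at -1.14. Their camera adjusted p was 1.95e-05, and the adjusted p = 0.597 with an estimated correlation. DPT and OGN had low means in diet H, 4.091 and 4.432, so background may enter their differences. Of 59 oxidative phosphorylation genes 56 lay lower, by a median of -0.18, with COX7A2 at -0.45 and UQCRHL at -0.67 (camera adjusted p = 4.87e-10; adjusted p = 0.537 with an estimated correlation). The sterol biosynthesis list had 14 of 15 members lower, including squalene synthase FDFT1 at -0.65 and lanosterol synthase LSS at -0.59, and T and NK lymphocyte markers had 23 of 26 lower, including CD3D at -0.47 and CD8A at -0.70. Both lists were called by camera (adjusted p = 0.00262 and 0.000975), with adjusted p = 0.577 with an estimated correlation for each. CD8A was at -0.45 without diet A replicate 1 and at -0.41 without diet H replicate 4, and CD3D was at -0.30 without diet A replicate 3.

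Other groups lay higher in diet H than in diet A. Among amino acid and peptide transporters 17 of 25 were higher, with a median of 0.22 (0.14 without diet A replicate 3), led by SLC38A2, a sodium-coupled neutral amino acid transporter, at 1.01 (SE 0.268), and SLC6A19, the main neutral amino acid carrier of the brush border, at 0.76 (SE 0.232). SLC38A2 was higher in each of the 4 diet H birds than in all diet A birds, its limma adjusted p was 0.204, and 1 of the 25 passed when adjusted over the list alone. The camera adjusted p of the list was 0.00688, and the adjusted p = 0.366 with an estimated correlation. Of 23 enteroendocrine genes 19 were higher, among them secretogranin SCG2 at 0.75 and RIMBP2 at 0.40 (camera adjusted p = 0.000164; adjusted p = 0.366 with an estimated correlation). RIMBP2 had low means, 4.246 in diet A and 4.647 in diet H. Immediate early genes had 12 of 16 members higher and a median of 0.54, with the nuclear receptor NR4A3 at 0.90 and FOSL2 at 0.60. Of these genes 6 passed when adjusted over the list alone and 0 over all probe sets in limma, where 7 had an unadjusted p under 0.05. Their camera adjusted p was 0.000379, and the adjusted p = 0.366 with an estimated correlation. In the inflammatory list the chemokine IL8L1 differed by 1.79 (SE 0.418) and NFKB1 by 0.53 (SE 0.142), and 7 of 34 members passed when adjusted over the list alone, although the median of the list was 0.05 (up to 0.13, without diet H replicate 4). Brush border and luminal peptidases had 14 of 17 members higher, among them the metalloprotease MEP1B at 0.89 and ACE at 0.48. These last lists had camera adjusted p of 0.0125 and 0.0297, and both had adjusted p = 0.577 with an estimated correlation.

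In all, camera with its preset correlation called 12 of 38 lists between diets A and H, and 8 of the 35 possible splits of these 8 arrays called at least as many. Leaving out a single bird ended 5 of the 12 calls, with camera adjusted p up to 0.121: amino acid transporters (diet A replicate 1), peptidases (diet A replicates 1 and 3, diet H replicate 3), inflammatory genes (diet H replicates 2 and 3), sterol genes (diet A replicate 3) and lymphocytes (diet A replicate 3, diet H replicate 4). Numbers in the sample titles fell into 2 ranges, up to 25 and over 25, with 2 birds of each diet in each, and within a range the numbers followed the order A, E, F, H. With this range as a block, limma called 111 probe sets between diets A and H, 55 higher and 56 lower in diet H, and within each range alone, with 2 birds against 2, it called 0, where 3220 and 1516 had an unadjusted p under 0.05. Some of the 111 gave the same fold change and adjusted p, such as probe sets 15387666, 15387667 and 15387668 (-0.619, limma adjusted p = 0.0436), so 111 is not a count of independent transcripts. The block ended the call of the peptidase list (camera adjusted p = 0.0524). With the title number as a linear covariate in place of the block, the peptidase and crypt lists were not called (camera adjusted p = 0.528 and 0.0658). PURG differed by 1.02 in the lower range and by 0.75 in the upper range. The ribosomal list had medians of -0.71 and -0.28 in the lower and upper ranges, and the matrix list had -1.50 and 0.02.

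**Figure D2:**
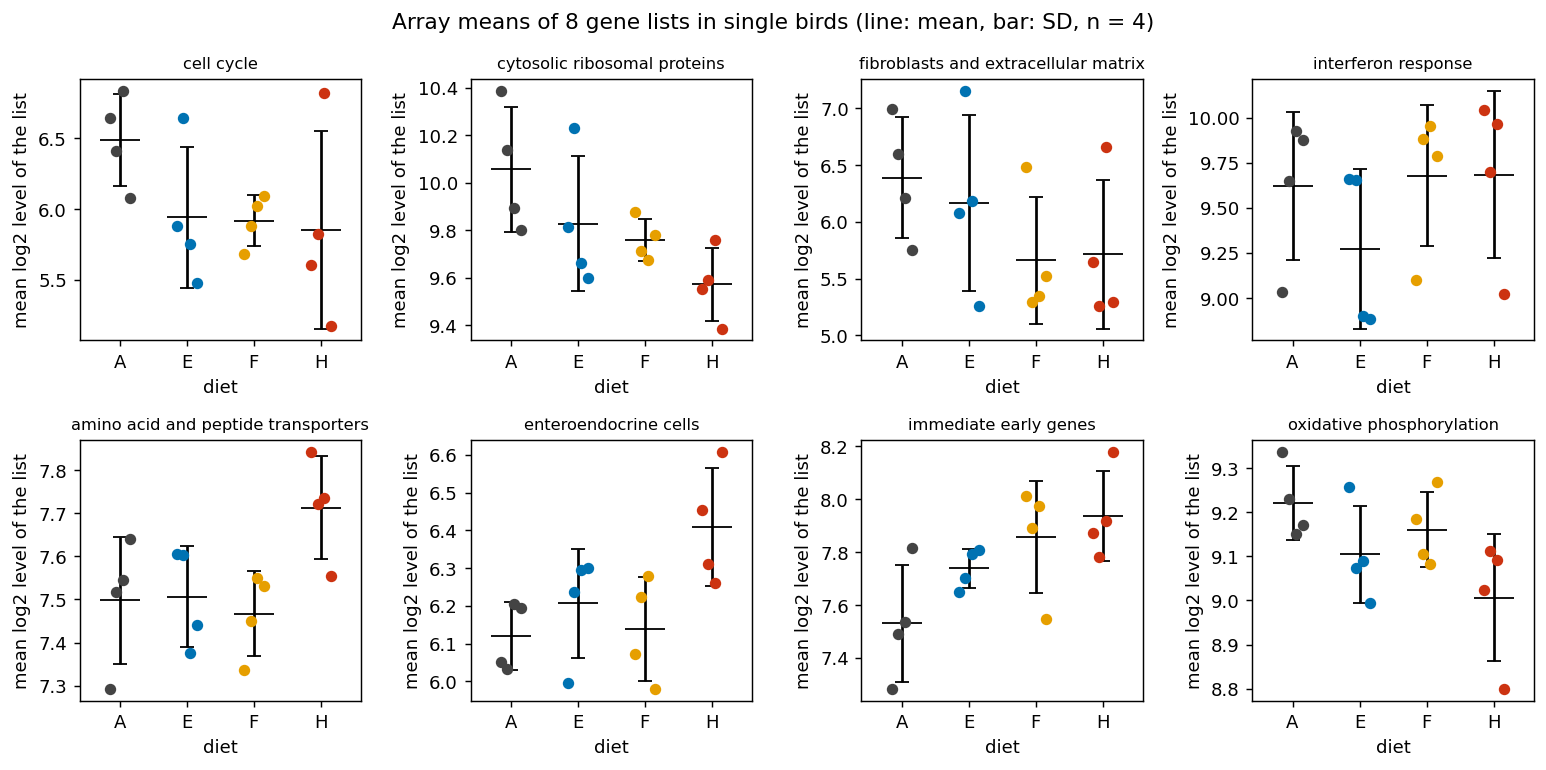
Mean log2 level of 8 gene lists (vertical axis) on each array by diet (horizontal axis); points are birds, the line is the mean and the bar the SD of 4 birds. The ribosomal list had means of 10.06 in diet A and 9.57 in diet H, and the cell cycle list had an SD of 0.70 in diet H.

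Between diets A and E, LOC420748, TMEM86A and DPYS were the named genes on the higher side of diet E, with log2 differences of 0.53 (SE 0.104), 1.31 (SE 0.261) and 0.72 (SE 0.146). On the lower side were ARPC5L, a subunit of the actin-nucleating Arp2/3 complex, at -0.50 (SE 0.114), the glycosyltransferase C1GALT1 at -0.75 (SE 0.189) and MRPS10 at -0.52 (SE 0.133). No gene passed: limma called 0 probe sets, 1605 had an unadjusted p under 0.05, and the smallest adjusted p was 0.284. Cell cycle genes lay lower in diet E, 51 of 53 of them, with the replication helicase subunit MCM4 at -0.84 and cyclin CCNE2 at -0.71. The array mean of this list was 5.94 ± 0.50 in diet E against 6.49 ± 0.32 in diet A (SD, n = 4), and the median difference of -0.62 was -0.40 without diet E replicate 4, -0.27 in the lower and -0.90 in the upper range of title numbers. Ribosomal protein genes lay lower in 51 of 52 cases, with RPL10A at -0.55 and RPL39L at -0.34, and oxidative phosphorylation genes in 52 of 59, with NDUFC2 at -0.42 and NDUFAF7 at -0.23. The camera adjusted p of these lists was 2.78e-14, 6.63e-11 and 5.3e-05, and each call was lost with adjusted p = 0.737 with an estimated correlation. RPL10A was at -0.34 without diet A replicate 1.

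Interferon response genes were lower in diet E for 26 of 27 members, with the RNA sensor IFIH1 at -0.50 and the ubiquitin ligase DTX3L at -0.31, but within the lower range of title numbers the median of the list was 0.26, against -0.93 in the upper range. T and NK lymphocyte markers lay lower for 23 of 26 members, with the chemokine receptor CCR7 at -0.59 and the chemokine XCL1 at -0.53. Goblet cell genes were higher for 18 of 22 members, with CLCA2 at 0.50 and the mucin MUC1 at 0.44, and tight junction and adhesion genes for 20 of 24, with claudin CLDN1 at 0.26 and MARVELD3 going the other way at -0.25. CLCA2 had low means, 4.023 in diet A and 4.52 in diet E. XCL1 was at -0.30 without diet E replicate 4, and CLDN1 at 0.15 without diet A replicate 4. The camera adjusted p was 0.000142 for interferon, 0.00272 for lymphocytes, 0.0128 for goblet cells and 0.0472 for tight junctions. All 7 calls between diets A and E were lost, each with adjusted p = 0.737 with an estimated correlation. No member of these lists passed over all probe sets or adjusted over the list alone, and 27 of the 35 splits of the 8 arrays called at least 7 lists. A single bird left out ended 3 of the calls, with camera adjusted p up to 0.322: lymphocytes (diet A replicates 1 and 3), goblet cells (diet A replicate 1, diet E replicate 3) and tight junctions (diet A replicate 1, diet E replicates 1, 3 and 4, diet F replicate 3, diet H replicates 1 and 3).

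Between diets A and F, TMEM86A had a log2 difference of 1.11 (SE 0.261), PRDM4, a zinc finger transcription factor, 0.49 (SE 0.114) and PURG 0.47 (SE 0.104), all higher in diet F. On the lower side were DPT at -1.71 (SE 0.398), MRPS10 at -0.63 (SE 0.133) and CINP, a partner of cyclin-dependent kinases, at -0.55 (SE 0.114). None passed: limma called 0 probe sets, with 1421 at an unadjusted p under 0.05 and a smallest adjusted p of 0.573. The count was 2 without diet F replicate 1. DPT and CINP had low means in diet F, 3.797 and 4.153, so background may enter their differences. OLFM4, a marker of crypt stem cells, had the widest gap among the named genes, with 9.92 ± 0.83 in diet A and 5.97 ± 1.09 in diet F (SD, n = 4; log2 difference -3.95, SE 1.11, limma adjusted p = 0.721). It belongs to the crypt list, where 17 of 23 genes lay lower, SLC12A2 among them at -0.72.

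Cell cycle genes lay lower in diet F for 52 of 53 members, including the kinesin KIF2C at -0.88 and PLK4, the kinase of centriole duplication, at -0.87. Ribosomal protein genes did so for 51 of 52, with RPL23A at -0.51 and RPL35A at -0.42, and matrix genes for 26 of 30, with OGN at -1.35 beside DPT. Immediate early genes had 13 of 16 members higher, with the phosphatase DUSP1 at 0.72 and the transcription factor EGR1 at 0.37. Of the matrix genes 1 passed when adjusted over the list alone, and of the immediate early genes 4 did. OGN, like DPT, had a low mean in diet F, 4.224. Goblet cell genes were higher for 16 of 22, with TFF3 at 0.39 and CREB3L1 at 0.38, and peptidases for 12 of 17, with MEP1B at 0.66 and ACE at 0.50. The camera adjusted p was 1.38e-17 for cell cycle, 1.25e-18 for ribosomal, 2.07e-09 for matrix, 0.000248 for immediate early, 0.013 for crypt, and 0.0218 for goblet and peptidase genes. None of these 7 calls held with an estimated correlation: adjusted p = 0.892 with an estimated correlation for peptidases, 0.887 for matrix genes and 0.753 for the other lists. At least 7 lists were called by 14 of the 35 splits of the 8 arrays. The immediate early, ribosomal and goblet medians were 0.59, -0.46 and 0.23 in the lower range of title numbers. In the upper range they were 0.09, -0.14 and 0.07. With the title number as a linear covariate, the peptidase, crypt and goblet lists were not called (camera adjusted p = 0.659, 0.622 and 0.124). The calls of 3 lists ended without a single bird, with camera adjusted p up to 0.324: goblet cells (diet A replicate 1, diet F replicate 3), crypt genes (diet A replicates 1 and 2) and peptidases (diet A replicates 1 and 3, diet F replicates 3 and 4).

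Between diets E and F, MIR20B, EGR1 and KPNA1, an importin of the nuclear pore route, were the named genes on the higher side of diet F, with log2 differences of 0.54 (SE 0.15), 0.47 (SE 0.122) and 0.35 (SE 0.102). TOR1B, an ATPase of the endoplasmic reticulum, ANKRD31 and LOC420748 were on the lower side at -0.62 (SE 0.158), -0.45 (SE 0.109) and -0.40 (SE 0.104). Their limma adjusted p was 1. The smallest in this pair was 0.147, limma called 0 probe sets, and 614 had an unadjusted p under 0.05, where 1040 would be expected by chance. The count was 10 without diet H replicate 1 and 5 without diet F replicate 4. Interferon genes lay higher in diet F for 26 of 27 members, with a median of 0.41, including IFIH1 at 0.57 and IFI6 at 0.48, but the median was -0.13 in the lower and 0.95 in the upper range of title numbers. Matrix genes lay lower in diet F for 29 of 30, with DPT at -0.80 and the protease inhibitor TIMP3 at -0.35. Endothelial genes did so for 20 of 21, with the transcription factors ERG at -0.44 and TAL1 at -0.25. TAL1 had low means, 4.328 in diet E and 4.076 in diet F. So did MIR20B (3.777 and 4.313) and ANKRD31 (3.409 and 2.955), and DPT was at 3.797 in diet F. Without diet E replicate 2 DPT was at -0.52, TIMP3 at -0.18 and ERG at -0.28, and neither the matrix nor the endothelial list was called (camera adjusted p = 0.128 and 0.264). TIMP3 was at -0.23 without diet F replicate 4, IFIH1 at 0.87 without diet F replicate 1, and IFI6 at 0.24 and the interferon median at 0.25 without diet E replicate 4.

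Mast cell and thrombocyte genes lay lower in diet F for 9 of 9, with histidine decarboxylase HDC at -0.48 and F13A1 at -0.28, which were at -0.20 and -0.11 without diet E replicate 2. Smooth muscle genes lay lower for 13 of 16, with MYOCD at -0.27 and TPM1 the other way at 0.24, a call that ended with the range as a block (camera adjusted p = 0.0624). Smaller shifts were called for the proteasome (median 0.07, PSMD14 at 0.35 and PSMA4 at 0.28), oxidative phosphorylation (median 0.05, COX8A at 0.30 and ATP5B at 0.28) and ribosomal proteins (median -0.07, RPL35A at -0.23 and RPL32 at -0.22), and each of these calls was lost with adjusted p = 0.958 with an estimated correlation. The medians of these last lists were -0.11, -0.02 and -0.22 in the lower range and 0.34, 0.15 and 0.08 in the upper. Leaving out single birds, these medians ran from 0.01 to 0.16, from 0.03 to 0.10 and from -0.16 to 0.09, the last without diet E replicate 2, where COX8A was at 0.13 and RPL35A and RPL32 at -0.12. The 8 lists had camera adjusted p between 1.45e-08 and 0.0345, all lost with adjusted p = 0.958 with an estimated correlation, and 23 of the 35 splits called at least 8 lists. The interferon call alone held without each single bird. The others ended with camera adjusted p up to 0.774: mast cells (diet E replicate 2, diet F replicate 3), smooth muscle (diet A replicate 3, diet E replicates 2 and 3, diet F replicates 2, 3 and 4), proteasome (diet E replicates 3 and 4, diet F replicates 2, 3 and 4), oxidative phosphorylation (diet E replicates 2, 3 and 4, diet F replicates 1 and 4), ribosomal proteins (diet F replicates 2, 3 and 4, and diet E replicate 2 with the sign turned), and matrix and endothelium (diet E replicate 2).

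Between diets E and H, ASPA, the enzyme that cleaves N-acetylaspartate, had a log2 difference of 1.73 (SE 0.364), PURG 0.63 (SE 0.104) and the interleukin 4 receptor IL4R 0.57 (SE 0.125), higher in diet H. MIR1631 at -0.63 (SE 0.141), ZNF71 at -0.56 (SE 0.128) and LOC420748 at -0.52 (SE 0.104) were on the lower side. Limma called 0 probe sets, 1981 had an unadjusted p under 0.05, and the smallest adjusted p was 0.255. Without diet A replicate 2, whose array enters only the shared spread, the count was 2. Amino acid and peptide transporters were higher in diet H for 19 of 25, with SLC38A2 at 1.11 (SE 0.268) and SLC36A4 at 0.34 (SE 0.167; 0.22 without diet E replicate 2), and 1 passed when adjusted over the list alone. Enteroendocrine genes were higher for 20 of 23, with SCG2 at 0.58 and carboxypeptidase E (CPE) at 0.43, and interferon genes for 25 of 27, with IFIH1 at 0.79 and PARP9 at 0.65.

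Ribosomal protein genes were lower in diet H than in diet E for 50 of 52, with RPL35A at -0.41 and RPL23A at -0.36, and oxidative phosphorylation genes for 47 of 59, with UQCR11 at -0.40 and NDUFB6 at -0.32. Sterol genes were lower for 13 of 15, with FDFT1 at -0.59 and DHCR7 at -0.31. Without diet E replicate 1 FDFT1 was at -0.28 and NDUFB6 at -0.21, and without diet E replicate 2 RPL23A was at -0.21. Matrix genes were lower for 26 of 30, with the matrix Gla protein MGP at -1.39 (SE 0.832; -0.67 without diet E replicate 2 and -2.19 without diet E replicate 4) and COL5A1 at -0.48. The sterol and matrix medians were -0.54 and -1.24 in the lower range of title numbers and 0.06 and 0.23 in the upper. The 7 lists had camera adjusted p between 5.92e-10 and 0.0327. With an estimated correlation all were lost: adjusted p = 0.827 with an estimated correlation for matrix and oxidative phosphorylation genes and 0.811 for the others. At least 7 lists were called by 25 of the 35 splits. Without a single bird 5 of these calls ended, with camera adjusted p up to 0.772: amino acid transporters (diet H replicate 1, diet E replicates 3 and 4), enteroendocrine genes (diet E replicate 1, diet H replicates 1 and 4), sterol genes (diet E replicate 1, diet H replicates 1 and 2), oxidative phosphorylation (diet E replicates 1 and 3, diet H replicate 4) and matrix genes (diet E replicate 2, diet H replicates 2 and 4).

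Between diets F and H, PLCL1 had a log2 difference of 0.51 (SE 0.132), UFM1, a ubiquitin-like modifier, 0.46 (SE 0.115) and PURG 0.41 (SE 0.104), higher in diet H. ABHD11, a mitochondrial hydrolase, was at -0.57 (SE 0.123), FSCN2 at -0.47 (SE 0.119) and G6PC, glucose 6-phosphatase, at -0.47 (SE 0.117). Limma called 0 probe sets, 1096 had an unadjusted p under 0.05, and the smallest adjusted p was 0.753. Enteroendocrine genes were higher in diet H for 21 of 23, with CPE at 0.58 and RIMBP2 at 0.42, and amino acid and peptide transporters for 19 of 25, with SLC38A2 at 0.75 and the lysosomal SLC38A9 at 0.36. These lists had camera adjusted p of 5.54e-06 and 0.00185, and adjusted p = 0.258 with an estimated correlation for both. Genes of protein folding in the endoplasmic reticulum were higher for 21 of 27, with the kinase EIF2AK3 at 0.37 and DNAJC3 at 0.28, although their median was 0.39 in the lower and -0.13 in the upper range of title numbers.

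Sterol genes were lower in diet H than in diet F for 14 of 15, with FDFT1 at -0.63 and their regulator SREBF2 at -0.31. Oxidative phosphorylation genes were lower for 54 of 59, with COX8A at -0.36 and NDUFB6 at -0.34, and ribosomal protein genes for 50 of 52, with RPL24 at -0.33 and RPS20 at -0.27. T and NK lymphocyte markers were lower for 20 of 26, with CD8A at -0.81 and CD3D at -0.39, or -0.53 and -0.25 without diet H replicate 4. That call ended with the range as a block (camera adjusted p = 0.0729). These lists and the folding list had camera adjusted p between 4.57e-07 and 0.0488, and adjusted p = 0.939 with an estimated correlation for each. No member passed over all probe sets or adjusted over the list alone, and 23 of the 35 splits called at least 7 lists. Leaving out a bird ended the calls of the folding list (diet F replicate 1, diet H replicate 1) and of the lymphocytes (diet E replicates 1, 2, 3 and 4, diet F replicates 2 and 3, diet H replicates 2 and 4), with camera adjusted p up to 0.94.

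**Figure D3:**
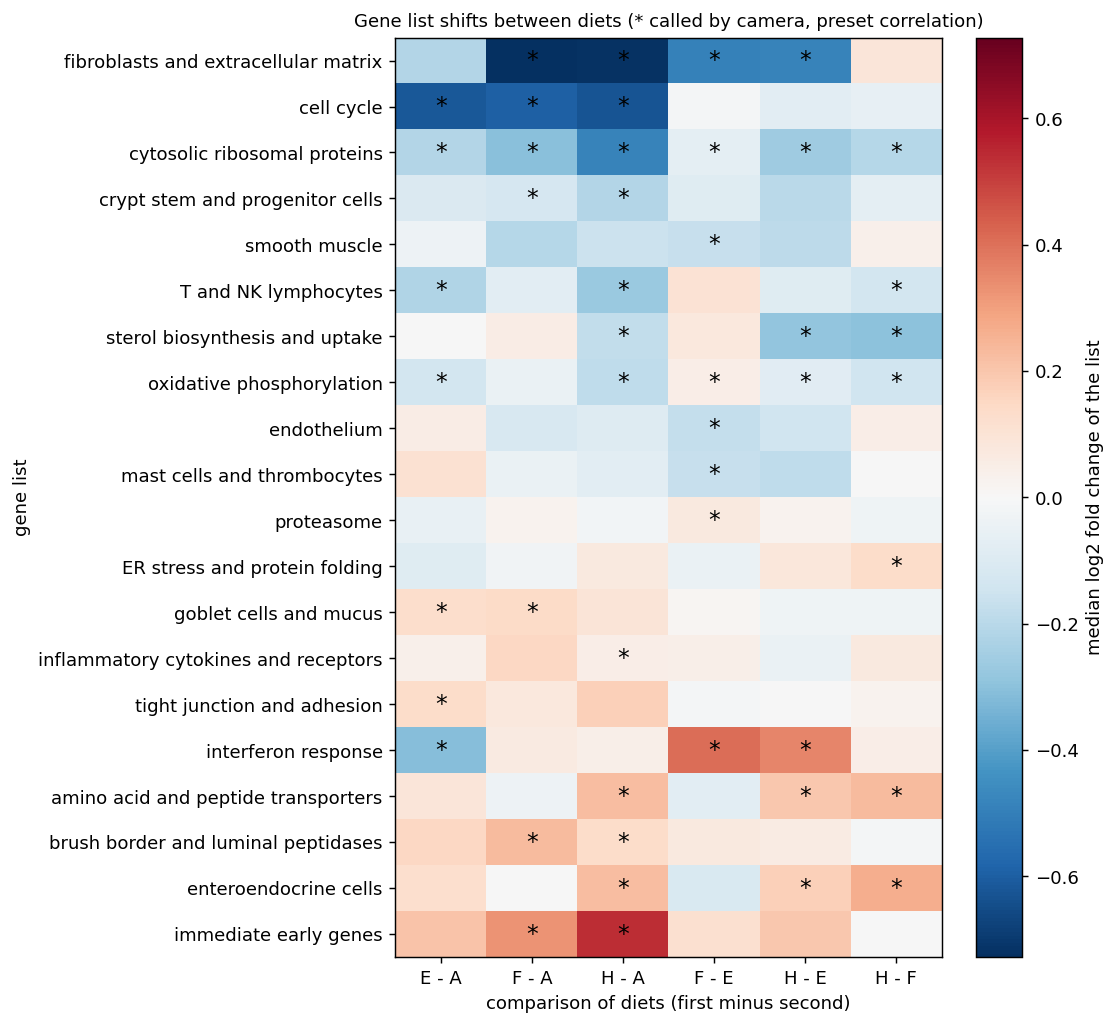
Median log2 fold change (colour scale) of the 20 gene lists (rows) that camera called in at least 1 of the 6 comparisons (columns, first diet minus second); asterisks mark calls with the preset correlation, none of which held with an estimated correlation. The cell cycle list had medians of -0.62 (-0.40 without diet E replicate 4), -0.60 and -0.63 (-0.37 without diet H replicate 4 and -1.04 without diet H replicate 3) for diets E, F and H against diet A.

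Of the transporters picked beforehand because the title speaks of digestibility, SLC15A1 is the intestinal di- and tripeptide transporter, and SLC5A1 is the sodium glucose cotransporter. SLC15A1 had means of 10.93 ± 0.47, 11.47 ± 0.19, 11.23 ± 0.29 and 11.50 ± 0.23 in diets A, E, F and H (SD, n = 4). Its log2 difference from diet A was 0.54 (SE 0.211, limma adjusted p = 0.613) in diet E, 0.30 (SE 0.211) in diet F and 0.57 (SE 0.211, limma adjusted p = 0.318) in diet H. Without diet A replicate 1 these differences were 0.34, 0.10 and 0.37, and that of diet F was 0.16 without diet F replicate 3 and 0.46 without diet A replicate 4. SLC5A1 lay between 12.44 and 12.62 in all diets, and its largest difference was 0.18 (SE 0.141) between diets A and H, or 0.09 without diet H replicate 4. The remaining 18 of the 38 lists were called in no pair, with medians between -0.22 and 0.28. They included the sugar transporters and brush border disaccharidases, lipid absorption, xenobiotic metabolism, the NRF2 and antioxidant genes, and markers of B lymphocytes and of macrophages and heterophils. The comparisons with diet A share its 4 arrays, so their similar shifts are not independent of each other.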

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

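Chosen after their results were seen were the tests of the title number as a linear trend behind the calls with the range block (PURG and the others), of chance among birds for the cell cycle list, of the lists in splits that keep 2 birds per range, and the exact test of diet A against the rest for that list. Single birds far from the other 3 of their diet were sought in 512 groups of 4, and 34 of these groups held one. Chance alone gives about 1 in 20 groups, which is not far below that share. Any single case below may therefore be chance, and genes that vary together in a bird are not separate cases.

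Diet H replicate 3 lay apart in genes of the endothelium and matrix lists. Its log2 levels were 5.52 for ERG against 4.48 to 4.65 in the other birds of its diet, 5.89 for OGN against 3.90 to 3.97, and 6.30 for COL5A1 against 5.74 to 5.82. OLFM4 was at 9.73 against 5.95 to 6.45, the endothelium list at 5.54 against 5.14 to 5.18, and the goblet cell list at 8.36 against 8.53 to 8.56. Diet E replicate 2 had ERG at 5.54 against 4.86 to 4.93, F13A1 at 5.33 against 4.60 to 4.71, and the T and NK lymphocyte list at 6.90 against 6.67 to 6.70. These were the 2 arrays with the lowest weights in limma, 0.602 and 0.540.

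Diet H replicate 4 had the first principal component at 47.76 against 5.71 to 8.05 in the rest of its diet. Its T cell markers CD8A and CD3D were at 7.10 against 8.18 to 8.29 and at 8.12 against 8.64 to 8.69. In the same bird ATP5B was at 11.69, NDUFC2 at 7.57 and CLCA2 at 4.61, against 12.24 to 12.29, 8.04 to 8.13 and 4.13 to 4.20. Diet F replicate 1 stood low in the interferon genes IFIH1 (7.84 against 8.95 to 9.13) and PARP9 (8.94 against 9.67 to 9.82), and had MARVELD3 at 7.26 against 7.10 to 7.12. Diet E replicate 1 stood high in squalene synthase FDFT1 (10.79 against 9.48 to 9.70) and in the sterol list (9.82 against 9.15 to 9.24).

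Single values apart from their diet were found in other birds too (range of the other 3 birds in parentheses). In diet H, replicate 1 had PRDM4 at 8.80 (8.47 to 8.51) and ASPA at 7.88 (7.45 to 7.48), and replicate 2 had RIMBP2 at 4.44 (4.70 to 4.73) and PLCL1 at 4.36 (4.60 to 4.64). In diet A, replicate 1 had PSMA4 at 9.12 (9.45 to 9.46), replicate 3 had MUC1 at 5.30 (5.48 to 5.50), and replicate 4 had KIF2C at 4.74 (5.39 to 5.49) and COX8A at 8.69 (8.42 to 8.45). In diet F, replicate 2 had CLDN1 at 5.83 (5.59 to 5.62), replicate 3 had ABHD11 at 6.71 (6.90 to 6.94), and replicate 4 had TIMP3 at 7.84 (8.26 to 8.35) and LUZP1 at 8.14 (8.47 to 8.49). In diet E, replicate 3 had CD3D at 8.79 (others up to 9.02) and SCG2 at 7.70 (7.07 to 7.17).

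Regrouping the birds tells little about the counts of probe sets, since a real count of 0 is reached by every grouping. Over the 4 diets limma called 0 (1696 at an unadjusted p under 0.05), so 100 of 100 groupings reached it by construction, and the highest other grouping called 2. For the pairs A and E, A and F, E and F, E and H, and F and H the limma count was 0 as well (1605, 1421, 614, 1981 and 1096 at an unadjusted p under 0.05), so 35 of 35 splits reached it by construction, and the highest others called 593, 2, 1, 485 and 1. The splits with 593 and 485 put the birds of the lower title number range against those of the upper range, which points to a structure of the samples; with the range as a block, limma called 0 in these pairs (2004 and 2903 at an unadjusted p under 0.05). Between diets A and H, 3 of 35 splits called at least the real 1 probe set and the highest other called 2, so chance is not excluded for that count. For the lists, 27, 14, 8, 23, 25 and 23 of 35 splits called as many as the real 7, 7, 12, 8, 7 and 7 (pairs A and E, A and F, A and H, E and F, E and H, F and H), and the highest others called 20, 15, 19, 17, 22 and 16. Chance is not excluded for these counts of lists. Many of these splits mix the title number ranges; in the 18 splits per pair that keep 2 birds per range on each side, with the range as a block, 14, 5, 7, 15, 12 and 14 called as many lists as the real 7, 8, 11, 7, 8 and 6, and the highest others called 16, 13, 19, 14, 18 and 16, but 18 splits are too few for a share under 0.05.

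The first pattern follows the sample titles and not the diets. Between the ranges of title numbers, with diets in the fit, limma called 1746 probe sets, 1335 higher and 411 lower in the upper range. Of 100 splits with 2 birds of each diet on each side, 1, the real one, called as many, and the highest other called 5. This argues against a chance split of single birds. The splits need not keep birds with neighbouring numbers together, as the real one does, so chance between such pairs is not excluded. With the array means of the matrix and cell cycle lists as covariates 1529 probe sets were called. That argues against these parts of the tissue as the whole cause. Quantile normalization left 1830, but it moved values by a median of only 0.023 against a median difference of 0.458 among the calls, so the normalization of the arrays was hardly tested and stays open. What the numbers stand for, and with it pen, order of sampling or order of handling, stays open too, and no biological explanation was tested.

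The second pattern is the rise from 1 to 111 calls between diets A and H once the range is a block. Of the 18 splits that keep 2 birds per range on each side, 1 called 111 and the highest other called 3, but 18 splits are too few for a share under 0.05. With the matrix and cell cycle lists added to the block, a median of 90.1% of the log2 fold changes of these probe sets was left (quartiles 82.6 and 99.7), which argues against these parts of the tissue as the whole cause. With the title number as a linear trend in place of the block, PURG kept 102.3% of its difference (0.90, 95% interval 0.655 to 1.148, limma adjusted p = 0.0337). This argues against that trend as its whole cause, but PURG was set apart, and the bound for its interval fixed, after the value was seen. The other 110 probe sets were not called and kept a median of 66.4% (quartiles 49 and 76), and 8 of them kept at least 90%. For the 110 as a set, diet and a trend along the number cannot be told apart. For all 111 a trend that starts anew in each range stays open, because within a range the numbers follow the order A, E, F, H. An effect of diet may account for part of the calls.

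The third pattern is the lower cell cycle list in diets E, F and H than in diet A, by 0.588 on the log2 scale for the mean of diet A minus that of the other 12 birds. An exact permutation over the 1820 choices of 4 birds gave a two-sided p of 0.0379 (n = 4 against 12), but diet A and this list were picked after the values were seen. Set against the highest t statistic of a diet against the rest in 100000 regroupings, the permutation p was 0.136 over the 4 diets for this list and 0.93 over the 4 diets and all 38 lists, so chance among birds is not excluded. With the matrix list as a covariate 58.7% of the difference was left, 0.345 with a 95% interval from -0.118 to 0.808, and with the title number 94.3% was left, 0.554 with an interval from -0.064 to 1.172. These intervals are too wide to decide on the matrix part of the tissue or on the numbers, and diet stays open as well.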

How the results depend on the processing

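Of the planned and added settings, the ones added after seeing the data were the linear title number, 1 copy of identical probe sets, leaving out diet E replicate 2 and diet H replicate 3, and the fits within a range of title numbers. For every change of a count below, the cause was not tested unless stated. Over the 4 diets, limma called 1 probe set, PURG, with median centring, the lowest 25% left out, the lowest 50% left out, probe sets without a single symbol left out, a trended and robust variance, array weights, and an adjusted p under 0.10. At an adjusted p under 0.25 the counts were 7 over the 4 diets, 563 between A and H and 10 between E and F. At an unadjusted p under 0.01 they were 345 over the diets and 329, 285, 752, 100, 429 and 160 for A and E, A and F, A and H, E and F, E and H, and F and H. Between diets A and H the count was 111 with the range block, 30 without the 2 arrays of lowest weight, and 0 with only these diets or within either range (3220 and 1516 there at an unadjusted p under 0.05), where fewer arrays were in the fit. Without those 2 arrays the count was 1 between diets A and E.

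Leaving out 1 bird at a time gave 0 to 1 probe sets between A and E, 0 to 2 between A and F, 0 to 2 between A and H, 0 to 10 between E and F, and 0 to 2 between E and H, and 0 throughout over the 4 diets and between F and H. The count was 1 between A and E without diet E replicate 2 and without diet H replicate 4, 2 between A and F without diet F replicate 1, 2 between A and H without diet A replicate 1 and 0 without diet H replicate 2. It was 10 and 5 between E and F without diet H replicate 1 and diet F replicate 4, and 2 between E and H without diet A replicate 2. Lists called in this way numbered 4 (without diet A replicate 1) to 14 (diet E replicate 2) for A and E, 4 (diet A replicate 1) to 13 (diet F replicate 1) for A and F, 5 (diet F replicate 2, 3 or 4) to 10 for E and F, and 4 (diet E or H replicate 1) to 14 (diet H replicate 3; 11 without diet E replicate 2) for E and H. The number of list calls over all pairs, 48, became 0 with an estimated correlation and 0 with fry, and each pair had 0 in both. By exact permutation of array means, 0, 2 and 4 of 38 lists had an unadjusted p under 0.05 for A and E, A and F, and A and H. For E and F, E and H, and F and H these were 0, 0 and 2. Of the 48 calls, 2 were lost with neighbouring title numbers as a random block and 11 with the linear title number. Lists called were 5 between E and F with quantile normalization and 4 with the lowest 50% left out, 4 between A and F with the linear title number, and 14 between A and E and 13 between E and H without the 2 arrays of lowest weight.

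The values that follow had the opposite sign to the reported one. SLC5A1 was at 0.00253 for F minus E with quantile normalization, -0.0617 for F minus A with the linear number, and for H minus E -0.00849 with array weights, -0.0247 with the linear number and -0.0304 without the 2 arrays. SLC15A1 for H minus E was -0.0377, -0.0877 and -0.0227 under those 3 settings and -0.217 in the lower range, and for F minus E it was 0.00721 in the upper range. Leaving out birds, SLC15A1 for H minus E ran from -0.0565 to 0.132 (negative without diet E replicate 2, diet E replicate 4 or diet H replicate 4), SLC5A1 from -0.147 to 0.0342 for F minus E (positive without diet F replicate 2 or diet E replicate 4) and from -0.0356 to 0.149 for H minus E (negative without diet E replicate 2 or diet H replicate 4), and the ribosomal list for F minus E from -0.157 to 0.0866, the last without diet E replicate 2. That list was also at 0.0866 without the 2 arrays and 0.0784 in the upper range. In the lower range alone, the interferon list was at 0.265 for E minus A and -0.132 for F minus E, IFIH1 at 0.0688 and -0.0129, DTX3L at 0.0788 and XCL1 at 0.172 for E minus A, and for F minus E oxidative phosphorylation was at -0.0222 and the proteasome at -0.108. In the upper range alone, the matrix list was at 0.0196 for H minus A and 0.231 for H minus E, the sterol list at 0.0621 for H minus E, the folding list at -0.127 for H minus F, and HDC at 0.0187 for F minus E. No paired analysis was possible because replicate numbers in the labels do not tie birds of different diets. Counted over all settings, 4345 comparisons of a named gene with its reported value kept their direction and side of the threshold, 12 came past it, 4 no longer passed and 22 had the opposite sign. For the lists these were 1327, 0, 245 and 11. The number of arrays, and 2 birds against 2 within a range, limit how small a difference can be called.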

Other observations

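The genes in this part, the setting without 2 arrays and the relation of the components to the title number were chosen after the values were seen. With the title number range as a block, the 111 probe sets called between diets A and H held 57 with a single symbol, 39 higher and 18 lower in diet H. On the higher side were ERRFI1 (log2 fold change 1.06, limma adjusted p = 0.0428), the immediate early receptor NR4A3 (0.90, 0.0491), the cytokine IL18 (0.83, 0.0436), the endothelial adhesion molecule PECAM1 (0.72, 0.0441), nonmuscle myosin MYH9 (0.61, 0.0436) and NFKB1 (0.53, 0.0436). PECAM1 does not stand for the endothelium list, which was not called in this pair. The list had means of 5.254 ± 0.193 in diet H and 5.369 ± 0.173 in diet A (SD, n = 4). On the lower side were the ribosomal protein genes RPL10A (-0.97, 0.0458), RPL24 (-0.72, 0.0458) and RPL35A (-0.60, 0.0496), and TOMM5 (-0.54, 0.0436), a part of the mitochondrial import pore. Without the block the adjusted p of these 10 genes was 0.197 to 0.257, and with the title number as a linear trend in its place none of them was called (adjusted p 0.4 to 0.66), with NR4A3 at 0.56, IL18 at 0.36, MYH9 at 0.33 and NFKB1 at 0.31. The remaining genes of the 10 were then at 0.887 (ERRFI1), 0.511 (PECAM1), -0.71 (RPL10A), -0.545 (RPL24), -0.404 (RPL35A) and -0.421 (TOMM5). Some other named genes lost nearly all of their difference with this trend. ARHGAP5 went from 0.617 with the block to -0.009, ZNF407 from 0.835 to -0.032 and CUL1 from 0.536 to 0.045. Of the 110 probe sets other than PURG, 8 kept at least 90%. Without diet E replicate 2 and diet H replicate 3, limma called 30 probe sets in this pair, 4 higher and 26 lower, and 5 of them were among the 111. The lower ones included the proliferation marker MKI67 (-1.73, adjusted p = 0.0456), cyclin CCND1 (-1.56, 0.0391), the exonuclease EXO1 (-0.83, 0.0452), and the matrix genes DPT (-1.82, 0.0391), OGN (-1.62, 0.0422) and ABI3BP (-1.21, 0.0340). Diet H replicate 3 had OGN at 5.89 against 3.90 to 3.97 in the other diet H birds. The diet A mean was 5.571. Leaving out this bird alone moved the cell cycle median from -0.63 to -1.04. Such calls therefore rest in part on which birds were left out. In the upper range of title numbers, with this bird kept, the matrix median between these diets was 0.02.

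Birds in the upper range of title numbers had higher levels of ZFC3H1, an exosome adaptor (log2 difference 0.94), the exocyst subunit EXOC1 (0.84), the cullin CUL1 (0.65), the cohesin subunit STAG2 (0.62) and VPS13A (1.14), with limma adjusted p from 4.46e-05 to 0.000194. Lower there were the helicase SNRNP200 (-0.42, adjusted p = 0.00218) and ND4L (-0.66, 0.0042), a subunit of complex I. CUL1 and ARHGAP5 (0.83 between the ranges) were also among the 111 probe sets called between diets A and H with the block. They were higher in diet H by 0.54 and 0.62. Camera called 3 lists between the ranges: the circadian clock genes, higher in the upper range with a median of 0.37 and 5 of 12 members called over all probe sets, the ribosomal proteins (-0.21) and the matrix genes (-0.39). All 3 calls were lost, with adjusted p = 0.912 with an estimated correlation. The ribosomal and matrix lists also lay lower in diet H than in diet A (medians -0.49 and -0.72), while the circadian list was not called in that pair. The difference between the ranges and that between diets A and H thus share some genes and lists.

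The first principal component, which held 22.8% of the variance, followed the title number over the 16 arrays (Pearson r = 0.846, permutation p = 3e-05, adjusted p = 9e-05; Spearman rho = 0.868, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 3e-05, over a family of 3 components). These permutations shuffle single birds, while the numbers come in neighbouring pairs of birds of a diet. If such birds are not independent, the permutation p is too small, so chance between pairs is not excluded. Without the 2 arrays farthest from the median number r was 0.847, and within the lower and upper ranges it was 0.880 and 0.544 (n = 8 each). Within a range the numbers follow the order A, E, F, H. There a trend along the number cannot be told apart from differences between diets. For components 2 and 3 r was 0.300 and 0.080, with permutation p of 0.265 and 0.765 (adjusted p = 0.398 and 0.765).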
